A study of Homo sapiens with 9 samples.

How the data were processed

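IGROV-1 cells were profiled on 9 Affymetrix whole-transcript arrays, 3 each labelled monolayer, spheroids and spheroids to monolayer. Per the labels' protocols, RNA was extracted with Trizol and labelled with biotin using Affymetrix whole-transcript reagents. Per the submitters' processing notes the arrays were handled with GCOS, Partek 6.2 and RMA, whose roles and order are not given there. The deposited table holds 1 value per probe set and array, read here as log2 RMA intensities: the notes do not state the base, but the values run from 1.59 to 14.21 with array medians of 4.97 to 5.03, which fits no linear intensity. RMA compresses ratios, so folds are those of the deposited log2 scale. Culture medium, density, duration and whether replicates were separate cultures are not given in the sources used here.

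Of 28869 probe sets, 19310 carried exactly 1 gene symbol in the array annotation and were used, 1752 carried several and 7807 were not listed, and both of these sets were left out. Entrez numbers of 19279 probe sets matched the RefSeq gene table of GRCh38.p14, used only for names, and 0 symbols needed an update. The build behind the array annotation is not named, so no coordinates are given. For 685 genes with more than 1 probe set the one with the highest mean over all arrays was kept, leaving 18377 genes, 16865 of them protein coding. No level filter was applied, and the table gives no detection values, so a low level cannot be told from background.

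Differences were estimated with limma 3.58.1 in R 4.3.3, as 1 linear model of the 3 groups (6 residual degrees of freedom, empirical Bayes variances with 3.91 prior degrees of freedom) and 3 comparisons: spheroids with monolayer, returned with spheroids and returned with monolayer. Tests were two-sided and p-values were adjusted over all genes by the method of Benjamini and Hochberg within each comparison, with 0.05 as threshold, and 2-fold (1 on the log2 scale) as the size threshold. A gene moved back when it was called between spheroids and monolayer and called in the opposite direction between returned cultures and spheroids. It was kept away when it was called in the same direction between returned cultures and monolayer. The percent kept is the log2 difference of returned cultures from monolayer over that of spheroids.

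Gene lists, 39 in number, the comparisons, the thresholds, the rule for naming genes and the alternatives were chosen before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation as alternative, and called at an adjusted p under 0.05 over the 39 lists. Members were also counted with p-values adjusted over the list alone. Named were, per comparison, the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap, up to 4 members of each called list and 2 of each other list, and 12 genes of prior interest (ALDH1A1, CTNNB1, FZD7, PROM1, KIT, CD44, SOX2, SCD, CDH1, VIM, HIF1A and MKI67). Symbols of small, uncharacterised or olfactory receptor loci, Y-linked genes and XIST were left out of the largest changes.

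Alternatives were quantile normalization, median centring, leaving out the third of genes with the lowest mean level, the mean of a gene's probe sets, a variance trend with robust moderation, no variance moderation, a fit of only the groups compared, a replicate block, leaving out each of the 9 arrays in turn, camera with an estimated correlation, fry, and only genes of at least 2-fold. Where leaving out an array left a group with fewer arrays, the spread was pooled over groups. Array weights and simulated shared arrays were added after seeing the data. The shared-array simulation drew 20 data sets with the fitted variances, with errors independent between genes and arrays.

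The steps were tested on simulated data of 18377 genes, 200 of them changed. For spheroids against monolayer 71.6%, 98.5% and 100% of genes changed by log2 0.5, 1 and 2 were recovered, for returned cultures against spheroids 70.2%, 100% and 100%, and for returned cultures against monolayer 77.6%, 98.5% and 100%. False calls numbered 3, 6 and 15 of 18177 unchanged genes in these comparisons.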

Results

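Gene expression of the ovarian cancer cell line IGROV-1 was measured on 9 arrays, 3 each from monolayer cultures, from spheroids and from cultures labelled spheroids to monolayer, called returned here. The series compares spheroids, which grow as multicellular aggregates, with monolayers, and ALDH1A1, an aldehyde dehydrogenase used as a stem cell marker, is a gene studied in such spheroids. The labels do not state the purpose of the returned cultures. On the first principal component, which held 51.2% of the variance, spheroid arrays lay at 25.1 to 28.5, monolayer arrays at -23.3 to -13.6 and returned arrays at -12.3 to -6.86. Monolayer replicate 2 stood apart from its group on the next component (16.3% of the variance), at 22.5 against 0.45 and 5.76. That component also set returned arrays, at -13.95 to -11.97, below every monolayer array and every spheroid array (1.43 to 4.69). Correlations across genes, which are not independent replicates, were 0.992 to 0.997 among monolayer arrays and 0.980 to 0.988 between monolayer and spheroid arrays. Of 18377 genes, 3357 differed among the 3 groups (limma's F test), against 2184 without spheroids replicate 2, 2224 without spheroids replicate 3 and 2119 without variance moderation. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

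**Figure D1:**
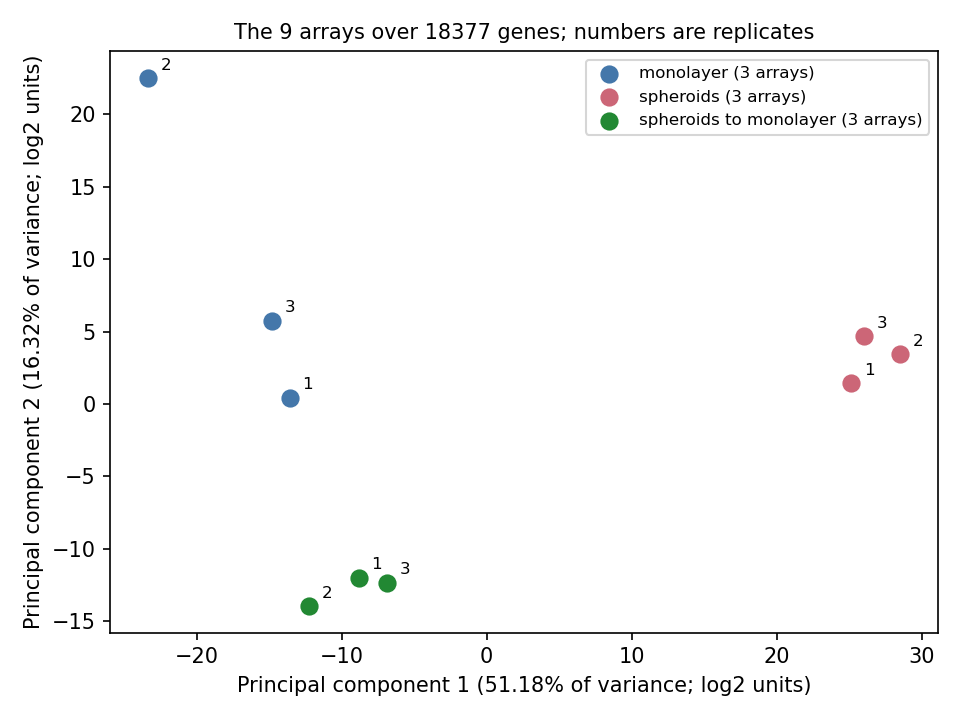
Each point is 1 array, placed by its scores on the principal components of the log2 values of all 18377 genes, with the percent of variance on each axis and 3 arrays per group. Spheroid arrays lie between 25.1 and 28.5 on the horizontal axis, where returned arrays lie nearer to monolayer. On the vertical axis returned arrays lie below both other groups.

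Spheroids carried more ALDH1A1 and KIT and less CD44 than monolayer, so genes used as stem cell markers moved in opposite directions. ALDH1A1 rose from a mean log2 level of 9.42 to 11.63, a difference of 2.21 ± 0.13 (standard error from limma, 3 arrays per group, 4.63-fold, adjusted p = 5.92e-06). KIT, the receptor for stem cell factor, rose by 2.62 ± 0.14 (6.13-fold, adjusted p = 3e-06), and PROM1, which encodes CD133, by 0.85 ± 0.089 (adjusted p = 0.000167). CD44, a hyaluronan receptor, fell by 1.5 ± 0.087 (2.83-fold, adjusted p = 4.68e-06). The mesenchymal filament gene VIM fell by 0.92 (adjusted p = 2.06e-05), the epithelial cadherin CDH1 fell by 0.89 from a low level of 5.62 (adjusted p = 0.00364), and the Wnt receptor FZD7 rose by 0.61 (adjusted p = 0.00439). CTNNB1, SOX2, SCD, HIF1A and the proliferation marker MKI67 did not pass the test (adjusted p = 0.694, 0.123, 0.513, 0.424 and 0.184), with differences of 0.043, 0.38, -0.13, 0.15 and -0.30. The difference of CTNNB1 changed sign under median centring, to -0.007.

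The largest increases in spheroids were those of the neuropeptide neurotensin (NTS, 3.68 ± 0.18) and of PDK4 (3.49 ± 0.22, 11.3-fold, adjusted p = 9.33e-06), a kinase that restrains pyruvate oxidation. THSD7A, TUBA1A, TCP11L2, H2BC12, the protocadherin PCDHB16 and the semaphorin receptor PLXNA4 rose by 2.05 to 2.97. The largest decrease was that of the collagenase MMP1, which was 19.8-fold lower (log2 10.75 to 6.44, adjusted p = 0.000137). The adhesion molecule CEACAM1, the fatty acid ligase ACSL5, the actin bundler LCP1 and the urokinase PLAU followed, with differences of -3.52 to -2.97, then the keratins KRT15 and KRT24 and the enzymes SQOR and XDH. In each of these genes the 3 spheroid arrays lay wholly on 1 side of the 3 monolayer arrays.

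Across all 18377 genes, 3365 differed between spheroids and monolayer, 1801 higher and 1564 lower, and 331 of them by at least 2-fold (173 higher, 158 lower). Groups did not overlap in 31.04% of genes, where chance gives 10%. The balance of directions follows the scaling: 53.5% of calls were higher as deposited and 41.5% after median centring. Of 112 named genes called here, 101 were called under each alternative that was run, but the naming favoured large differences. The count of all genes was 2355 without spheroids replicate 2, 2390 without variance moderation and 4693 with array weights. Without spheroids replicate 2, 2293 of the 3365 were called again in the same direction. Called genes differed by a median of 0.49 on the log2 scale, and the number of arrays limits the precision for smaller differences.

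**Figure D2:**
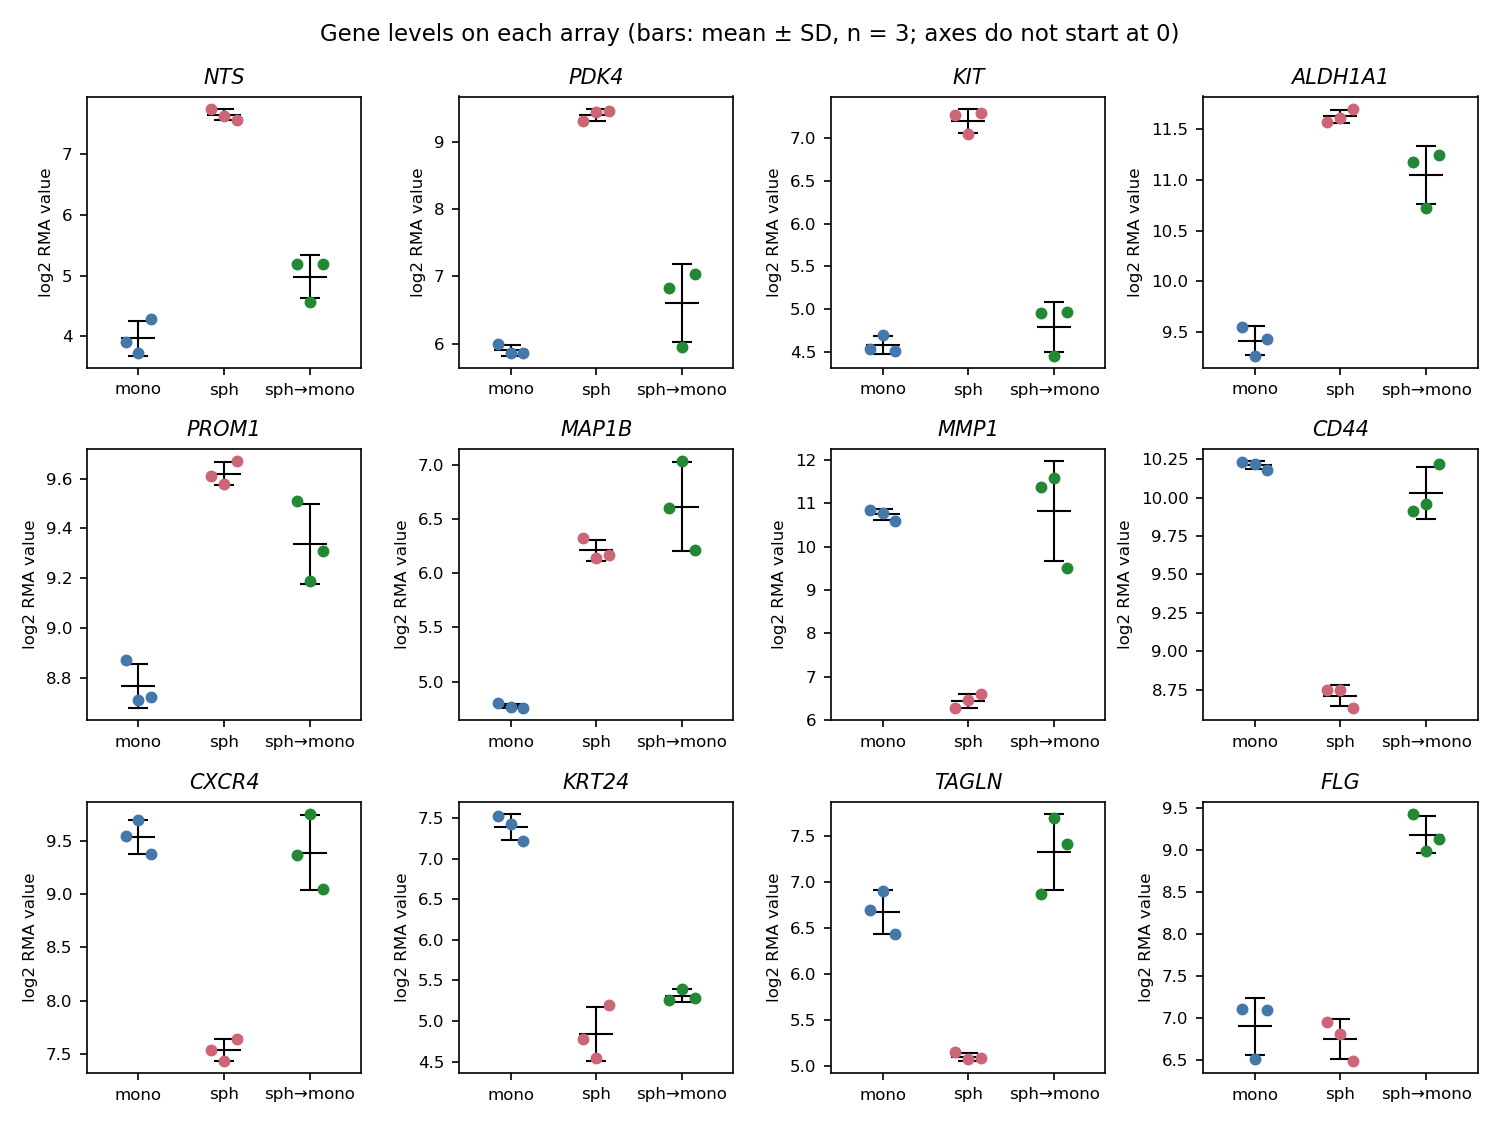
Log2 levels of named genes on each array, 1 point per array and 3 arrays per group, with bars for the group mean and standard deviation. ALDH1A1 lies at 9.42 in monolayer, 11.63 in spheroids and 11.05 in returned cultures, whereas KIT falls back to 4.797.

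Of 39 gene lists fixed before the data were examined, 9 were lower in spheroids and 3 higher by camera with its preset correlation. With a correlation estimated from the data camera called 0 lists (smallest adjusted p = 0.188, 4 lists at an unadjusted p under 0.05), whereas limma's fry, which tests direction only and not against other genes, called 22. For each called list the estimated correlation gave the highest adjusted p of its 20 alternatives, and the lowest is given beside it. Lists of hypoxia-induced and glycolysis genes were called lower in spheroids. HK2, ALDOC and ENO2 are members of both, so the calls of these lists are not independent in any comparison. Hypoxia-induced genes fell in 21 of 34 and the other 13 did not pass (median -0.48, adjusted p = 1.03e-09, lowest 9.67e-12, adjusted p = 0.463 with an estimated correlation), among them the chemokine receptor CXCR4 (-1.99), ALDOC, PFKFB4 and the clock repressor BHLHE40 (-1.34). Adjusted over the list alone, 23 fell and 1 rose. Glycolysis genes fell in 13 of 16, such as the phosphofructokinase PFKP (-1.49 ± 0.064) and the hexokinase HK2 (-1.27), and only LDHB rose (median -0.51, adjusted p = 3.48e-09, lowest 3.46e-20, adjusted p = 0.188 with an estimated correlation; adjusted over the list alone 14 fell and 1 rose).

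Cell cycle genes were lower in spheroids too. DNA replication genes fell in 19 of 34, for example the ribonucleotide reductase subunit RRM2 (-0.90) and the licensing factor CDT1 (-0.86), with a median of -0.41 (adjusted p = 3.71e-09, lowest 1.39e-12, adjusted p = 0.496 with an estimated correlation). Mitosis genes fell in 15 of 29, among them the checkpoint kinase BUB1 (-0.84), CDC20 (-0.81), AURKA and PLK1, with a median of -0.45 (adjusted p = 7.75e-09, lowest 1.58e-14, adjusted p = 0.469 with an estimated correlation). Adjusted over the list alone, 22 replication and 19 mitosis genes fell. The remaining members of both lists did not pass the test. Monolayer replicate 2, the array that stood apart, held less of these genes than the rest of its group: its mean log2 level was 7.80 for mitosis, against 8.11 and 8.22 in the other monolayer arrays and 7.64 to 7.67 in spheroids, and 7.93 for replication, against 8.12 and 8.20 and 7.71 to 7.74.

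Contractile, inflammatory and stimulus-induced genes were also lower in spheroids. Actin and SRF targets fell in 11 of 19, the same number as adjusted over the list alone, led by TAGLN (-1.57), the myosin light chain MYL9 (-1.003), FHL2 and TPM2 (median -0.40, adjusted p = 1.9e-07, lowest 7.09e-08, adjusted p = 0.188 with an estimated correlation). NF-kB targets and cytokines fell in 8 of 27 (10 adjusted over the list alone), with CXCL8 (-2.18), IL1A (-2.05), LIF and TNFAIP3 ahead (median -0.18, adjusted p = 8.48e-05, lowest 1.48e-05, adjusted p = 0.463 with an estimated correlation). Immediate early genes fell in 5 of 18, namely FOS (-1.49), IER3 (-1.20), FOSL1, DUSP1 and IER2 (adjusted p = 0.00364, lowest 0.0012, adjusted p = 0.534 with an estimated correlation, 8 adjusted over the list alone). Genes of complex I and oxidative phosphorylation fell in 6 of 37, such as NDUFA7 (-0.61) and NDUFB9 (-0.39), and NDUFA5 rose by 0.53 (median -0.17, adjusted p = 0.000878, lowest 0.000407, adjusted p = 0.188 with an estimated correlation; adjusted over the list alone 7 fell and 1 rose).

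TGF-beta targets were called by a narrow margin, with an adjusted p that rounds to 0.05 (lowest 0.00493, adjusted p = 0.463 with an estimated correlation). The members that fell were LTBP2 (-1.61), BHLHE40 and SKIL, 3 of 19, or 5 adjusted over the list alone. The list's call ended without monolayer replicate 1 (0.0757), monolayer replicate 3 (0.144), spheroids replicate 1 (0.0889) and spheroids replicate 3 (0.0776), and also under median centring (0.0658) and with a variance trend and robust moderation (0.056). The call of SKIL ended without monolayer replicates 1 and 3 (0.0807 and 0.0933) and spheroids replicates 1 and 2 (0.0902 and 0.0953).

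Higher in spheroids were stress response, p53 and lysosomal genes. ATF4 and amino acid response genes rose in 9 of 27, among them NUPR1 (1.88), the tryptophan tRNA ligase WARS1 (1.24), the glutathione-degrading CHAC1 (1.15) and DDIT3, while SLC7A5 and DDIT4 fell (median 0.21, adjusted p = 0.000811, lowest 0.00012, adjusted p = 0.534 with an estimated correlation; adjusted over the list alone 13 rose and 2 fell). Targets of p53 rose in 8 of 25, led by TP53INP1 (1.53 ± 0.11), GDF15 (1.45), ZMAT3 and SESN1, while the death receptor genes FAS and TNFRSF10B and the cyclin CCNG1 fell (median 0.25, adjusted p = 0.00483, lowest 0.000478, adjusted p = 0.188 with an estimated correlation; adjusted over the list alone 14 rose and 4 fell). Autophagy and lysosome genes rose in 11 of 28, such as WIPI1 (0.93), LAMP2 (0.79) and the cholesterol carrier NPC2 (0.78), and ATG16L1 fell (median 0.088, adjusted p = 0.00123, lowest 0.000315, adjusted p = 0.469 with an estimated correlation; adjusted over the list alone 12 rose and 1 fell).

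The other 27 lists were not called in spheroids, and several held members that moved in both directions. In the ALDH family, ALDH1A1, ALDH1L2 (1.29), ALDH6A1 and ALDH7A1 rose while ALDH1A3, ALDH1B1, ALDH2 and ALDH18A1 fell, 8 of 19 members and also 8 adjusted over the list alone (adjusted p = 0.673). Among 24 stem cell genes, PROM1, KIT, CD24, EPCAM and ALDH1A1 rose while CD44, LIN28A, SOX9, ITGA6 and ROR1 fell (adjusted p = 0.868). Of 25 Wnt targets, the protease MMP7 and SOX4 rose and CD44 fell (adjusted p = 0.651), and of 33 Wnt ligands and receptors WNT7B, FZD7 and LRP6 rose while FZD5 (-1.07) and ROR1 (-0.68) fell (adjusted p = 0.663). Epithelial junction and keratin genes rose in 8 and fell in 6 of 27, where the keratin KRT8 fell by 1.54 (adjusted p = 0.673). Integrins fell in 7 of 18, such as ITGA6 (-1.42) and ITGB4 (-1.25), and ITGA4, ITGAV and ITGB8 rose (adjusted p = 0.172). Of 24 mesenchymal genes TGM2 (-1.93), VIM and FBN1 fell and fibronectin (FN1) rose by 1.41 (adjusted p = 0.192). Interferon-stimulated genes rose in 6 of 30, such as PARP9 (1.06), and BST2 fell (adjusted p = 0.0747). The proapoptotic BCL2L11 (1.28) and CFLAR rose, and BIK (-1.01), TNFRSF10A and TNFRSF10B fell, among 22 apoptosis regulators (adjusted p = 0.36). Adjusted over the list alone, stem cell genes had 5 higher and 6 lower, epithelial genes 10 and 7, integrins 4 and 7 and interferon-stimulated genes 8 and 1, and the Wnt, mesenchymal and apoptosis lists had the same counts.

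Lists of other cell types were not called in spheroids either. Of 21 leukocyte markers those that fell were CD68 (-1.23) and LAPTM5 (-1.23), which encode lysosomal proteins, and of 15 endothelial markers it was the cadherin CDH5 (-1.85). Members beyond the largest differences of a list were named where a count was small, chosen after their values were seen. In 3 of the 39 lists, each not called, the median, the mean and the test differed in sign. The call of MMP7 ended without variance moderation (adjusted p = 0.0586).

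Returned cultures had regained much of the monolayer profile relative to spheroids, with MMP1 and CD44 up and KIT down, while ALDH1A1 fell by far less. MMP1 rose by 4.38 ± 0.43 (20.9-fold, adjusted p = 0.000159, 3 arrays per group), although returned replicate 3 lay at 9.50 and the other returned arrays at 11.38 and 11.59. CD44 rose by 1.32 ± 0.087 (2.497-fold, adjusted p = 1.92e-05) and VIM by 0.62 (adjusted p = 0.000268). KIT fell by 2.40 ± 0.14 (5.29-fold, adjusted p = 6.82e-06) and FZD7 by 0.66 (adjusted p = 0.00403). ALDH1A1 fell by 0.58 ± 0.13 (adjusted p = 0.0177), a call that ended without spheroids replicate 2 (0.0597), without spheroids replicate 3 (0.0708) and without variance moderation (0.0832). The desaturase SCD fell by 0.49 (adjusted p = 0.019), a call that ended without spheroids replicates 2 and 3 (0.0673 and 0.0804) and without returned replicates 1 and 3 (0.0749 and 0.0682). PROM1 (-0.28, adjusted p = 0.0678), CTNNB1, HIF1A, MKI67, SOX2 and CDH1 did not pass the test (adjusted p = 0.987, 0.967, 0.85, 0.514 and 0.771 for the last 5). CTNNB1 and HIF1A changed sign under median centring, from -0.003 to 0.05 and from -0.013 to 0.04.

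Behind MMP1, the largest increases from spheroids to returned cultures were those of ACSL5 (3.41 ± 0.18), LCP1 (3.25), the cytokines IL1A (3.05) and CXCL8 (2.88), the activation antigen CD69, the BMP antagonist NOG, PLAU, CEACAM1 and the transcription factor ETS1 (2.47 ± 0.10). The largest decreases were those of PDK4 (-2.79 ± 0.22, adjusted p = 4.38e-05), NTS (-2.67) and KIT, followed by FREM2, the kinase DCLK1, TCP11L2, the actin-severing SCIN, THSD7A, the matricellular CCN3 and PLXNA4 (-2.30 to -1.80). In each of these genes the arrays of the groups did not overlap.

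Between returned cultures and spheroids 2360 genes differed, 1121 higher and 1239 lower, with 257 of at least 2-fold (129 higher, 128 lower). Groups did not overlap in 31.4% of genes, where chance gives 10%. Higher genes made up 47.5% of calls as deposited and 61.6% after median centring. The count fell to 1506 without spheroids replicate 2 and 1551 without spheroids replicate 3, and to 1528 without variance moderation. Of 106 named genes called here, 89 held without each array in turn.

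Camera called 6 lists higher and 3 lower in returned cultures than in spheroids with its preset correlation. With an estimated correlation it called 0 (smallest adjusted p = 0.25, 3 lists at an unadjusted p under 0.05), and fry called 18. Contractile and growth-control genes were higher. Actin and SRF targets rose in 11 of 19, or 13 adjusted over the list alone, led by TAGLN (2.22), FHL2 (1.20), MYL9 (1.01) and TPM2 (median 0.38, adjusted p = 4.37e-08, lowest 2.27e-09, adjusted p = 0.25 with an estimated correlation). YAP/TAZ targets rose in 11 of 24, also 11 adjusted over the list alone, such as ANKRD1 (1.93), CCN1 (0.87), NT5E and FSTL1, and NUAK2 fell (median 0.20, adjusted p = 1.45e-05, lowest 7.22e-07, adjusted p = 0.46 with an estimated correlation). In spheroids against monolayer that list was not called, with 6 lower and 1 higher (adjusted p = 0.129).

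Inflammatory, stimulus-induced and metabolic genes were higher in returned cultures than in spheroids as well. NF-kB targets and cytokines rose in 11 of 27 (15 adjusted over the list alone), among them IL1A, CXCL8, TNFAIP3 (1.40) and CXCL1 (1.32), with a median of 0.28 (adjusted p = 3.78e-07, lowest 7.76e-08, adjusted p = 0.46 with an estimated correlation). Immediate early genes rose in 7 of 18 (10 adjusted over the list alone), such as FOS (1.18), IER3 (1.04) and FOSL1 (0.88), with a median of 0.43 (adjusted p = 2.33e-05, lowest 1.78e-07, adjusted p = 0.46 with an estimated correlation). Hypoxia-induced genes rose in 10 of 34 (13 adjusted over the list alone), led by CXCR4 (1.85), HK2 (0.94) and the glucose transporter SLC2A1 (0.67), with a median of 0.21 (adjusted p = 2.33e-05, lowest 8.86e-08, adjusted p = 0.569 with an estimated correlation). Glycolysis genes rose in 6 of 16 (10 adjusted over the list alone), including HK2, PFKP (0.70) and LDHA (0.36), with a median of 0.21 (adjusted p = 7e-05, lowest 5.09e-07, adjusted p = 0.46 with an estimated correlation).

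Lysosomal, interferon-stimulated and histone genes were lower in returned cultures than in spheroids. Autophagy and lysosome genes fell in 10 of 28, among them NPC2 (-0.83), LAMP2 (-0.76) and WIPI1 (-0.65), while ATG16L1 and NPC1 rose (adjusted p = 0.0009, lowest 0.000285, adjusted p = 0.46 with an estimated correlation; adjusted over the list alone 11 fell and 3 rose). The interferon-stimulated genes that fell were IFITM1 (-1.49), PARP9 (-0.93), IFIT1 (-0.75) and IFI6 (-0.51), 4 of 30 and also 4 adjusted over the list alone (adjusted p = 0.00607, lowest 0.00279, adjusted p = 0.46 with an estimated correlation). Core histone genes fell in 4 of 22, also 4 adjusted over the list alone (median -0.21, adjusted p = 0.000298, lowest 2.49e-06, adjusted p = 0.569 with an estimated correlation, 0.0649 by fry). They were H2AC6 (-0.58), H2AC13, H3C10 and H4C8. Except for H2AC6, these calls ended without spheroids replicate 2 (0.12, 0.138 and 0.141), spheroids replicate 3 (0.079, 0.158 and 0.0739), returned replicate 1 (0.0972, 0.142 and 0.142) and returned replicate 2 (0.161, 0.157 and 0.124). H2AC13 and H3C10 were also lost without monolayer replicate 1 (0.0664 and 0.0567) and 3 (0.07 and 0.0692), H4C8 without spheroids replicate 1 (0.123) and H2AC13 without returned replicate 3 (0.0895).

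Cell cycle lists, lower in spheroids than in monolayer, were not called between returned cultures and spheroids. Of 29 mitosis genes CDC20 (0.59, adjusted p = 0.00241) and BUB1 (0.40) rose, or 4 adjusted over the list alone (list adjusted p = 0.187), and the call of BUB1 ended without spheroids replicates 2 and 3 (0.0564 and 0.0639) and returned replicate 1 (0.0631). Stress lists held members of both directions: ATF4 and amino acid response genes rose in 5 and fell in 4 of 27, with SLC7A5 up by 1.06 and NUPR1 down by 1.38 (adjusted p = 0.524), and p53 targets rose in 4 and fell in 3 of 25 (adjusted p = 0.739). NRF2 targets rose in 6 and fell in 4 of 23, where the thioredoxin reductase TXNRD1 rose by 1.04 (adjusted p = 0.205). Epithelial junction and keratin genes rose in KRT7, KRT8 (1.11) and KRT18 and fell in 8 of 27 (adjusted p = 0.107). Integrins rose in 6 and fell in 4 of 18, where ITGA4 fell by 1.29 (adjusted p = 0.253). Adjusted over the list alone, ATF4 genes had 9 higher and 6 lower, p53 targets 5 and 3 and NRF2 targets 7 and 5, and the epithelial and integrin lists had the same counts. Markers of other cell types were not called, although the endothelial cadherin CDH5 rose by 1.86, the mesothelial LRRN4 by 1.64 and the squamous antiproteinase PI3 by 2.12. In 5 of the 39 lists, each not called, the median, the mean and the test differed in sign.

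Returned cultures were closer to monolayer than spheroids were, yet ALDH1A1 was still 3.10-fold higher in them than in monolayer (log2 9.42 to 11.05, difference 1.63 ± 0.13, adjusted p = 0.000448, 3 arrays per group). FLG, the epidermal protein filaggrin, rose by 2.28 ± 0.18 (4.87-fold, adjusted p = 0.000448) although spheroids had it at 6.75, near the monolayer level of 6.90. The microtubule protein MAP1B (1.84 ± 0.16), H2BC12 (1.88), the lipid transporter ATP10D (1.59), PI3 (1.54), SLFN5, SIPA1L2 and NIBAN1 (1.43) were also higher. KRT24 was 4.23-fold lower (-2.08 ± 0.15, adjusted p = 0.000224), and NRN1 (-1.42), the opioid-like precursor PNOC (-1.32), SHISA3 (-1.21), the integrin ITGB3 (-1.12), MMRN2 and the interferon-induced IFITM1 (-1.06) were lower. PROM1 stayed higher by 0.57 ± 0.089 (adjusted p = 0.0111).

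KIT (0.21, adjusted p = 0.51) and CD44 (-0.18, adjusted p = 0.364) no longer passed the test between returned cultures and monolayer, nor did FZD7, CTNNB1, SOX2, HIF1A and MKI67 (adjusted p = 0.887, 0.813, 0.606, 0.62 and 0.24). Other named genes were called by margins so narrow that the call ended when 1 array was left out. A spheroid array enters this comparison only through the pooled spread and its degrees of freedom. SCD fell by 0.62 (adjusted p = 0.0216, but 0.052 without monolayer replicate 1, 0.085 without returned replicate 1 and 0.0741 without returned replicate 3). CDH1 fell by 0.79 (adjusted p = 0.0325), which ended without monolayer replicate 3 (0.0592), spheroids replicates 1 and 3 (0.0655 and 0.0558) and returned replicates 1, 2 and 3 (0.114, 0.084 and 0.0685). VIM fell by 0.30 (adjusted p = 0.0463), a call that ended without any 1 of the 9 arrays (0.0551 to 0.151). TUBA1A (1.47) and TINAG (-1.09) ended without returned replicate 1 (0.05 after rounding and 0.0744), ALDOC (-1.22) without monolayer replicate 3 and returned replicate 1 (0.0521 and 0.0732), and CST1 (-1.80) without monolayer replicates 1 and 2, spheroids replicates 2 and 3 and returned replicates 1 and 2 (0.0502 to 0.0738).

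In all, 489 genes differed between returned cultures and monolayer, 225 higher and 264 lower, with 28 higher and 13 lower by at least 2-fold. Groups did not overlap in 15.3% of genes, where chance gives 10%. This count fell further than the others when single arrays were left out. It was 215 without monolayer replicate 3, and 183 and 318 without returned replicates 1 and 2. Without spheroids replicates 1, 2 and 3 it was 311, 313 and 295, although spheroid arrays enter this comparison only through the pooled spread and its degrees of freedom. Those falls thus do not show that the count depends on a particular array. The count was 112 without variance moderation, 108 with the spheroid arrays left out of the fit and 1120 with array weights. With only the groups compared in each fit, 106 of the 489 were called again. In spheroids against monolayer 2677 of 3365 were, and in returned cultures against spheroids 2181 of 2360. Differences between arrays had a standard deviation of 0.148 to 0.169 within spheroids, 0.184 to 0.288 within monolayer and 0.18 to 0.21 within returned cultures. Most of the 489 calls thus depend on a spread pooled with the spheroid arrays. Of 79 named genes called, 34 held without each array in turn and 21 under each alternative, among them ALDH1A1, FLG, MAP1B, ATP10D, PI3, SLFN5, KRT24, NRN1, PNOC and ITGB3.

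Camera called 9 lists lower and 4 higher in returned cultures than in monolayer, fry called 6 lower and 3 higher, and camera with array weights, added after seeing the data, 6 lower and 4 higher. With an estimated correlation the call of p53 targets was the 1 that held (adjusted p = 0.0202), and it also held under each of the other alternatives (lowest 1.04e-08). Targets of p53 rose in 4 of 25 and 12 adjusted over the list alone (median 0.25, adjusted p = 1.38e-08). They were the ribonucleotide reductase subunit RRM2B (0.75), GDF15 (0.74), TP53INP1 (0.69) and SPATA18 (0.51), single calls that all ended without returned replicate 1 (0.0606, 0.12, 0.053 and 0.0845). Without returned replicate 2 the calls of RRM2B (0.0528), GDF15 (0.115) and SPATA18 (0.065) ended, without monolayer replicates 1 and 3 those of GDF15 (0.0791 and 0.118) and SPATA18 (0.0608 and 0.0788), without each spheroid array that of GDF15 (0.0558 to 0.0639), and without returned replicate 3 that of SPATA18 (0.0839). The list as a whole was thus called more firmly than its members. ATF4 and amino acid response genes rose in 10 of 27, such as CHAC1 (1.05), WARS1 (0.76) and the amino acid transporter SLC7A5 (0.70), and DDIT4 fell (median 0.43, adjusted p = 2.43e-14, lowest 2.64e-18, adjusted p = 0.264 with an estimated correlation; adjusted over the list alone 18 rose and 1 fell).

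NRF2 targets and YAP/TAZ targets were higher in returned cultures than in monolayer as lists, on few single calls. NQO1 (0.63), GCLC (0.50) and the malic enzyme ME1 (0.45) rose among 23 NRF2 targets, or 8 adjusted over the list alone (adjusted p = 0.000188, lowest 1.17e-06, adjusted p = 0.429 with an estimated correlation, 0.0591 by fry). The calls of GCLC and ME1 ended without monolayer replicate 3 (0.0686 and 0.0548) and returned replicate 1 (0.071 and 0.0632), that of GCLC also without returned replicate 3 (0.0654) and that of ME1 without returned replicate 2 (0.0502). PTPN14, NT5E, CRIM1 and AMOTL1 rose among 24 YAP/TAZ targets, by 0.32 to 0.49, or 5 adjusted over the list alone (adjusted p = 0.000116, lowest 1.76e-06, adjusted p = 0.352 with an estimated correlation). PTPN14 was lost without monolayer replicate 3 (0.0696), NT5E without each array but monolayer replicate 1 (0.0546 to 0.0801), CRIM1 without each but returned replicate 2 (0.0585 to 0.0816) and AMOTL1 without each but monolayer replicate 2 (0.0559 to 0.0912).

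Cell cycle and histone lists were called lower in returned cultures than in monolayer, although the arrays overlapped for mitosis. DNA replication genes fell in 7 of 34 and 21 adjusted over the list alone, among them CDT1 (-0.77), the primase subunit PRIM1 (-0.76) and RRM2 (-0.60), with a median of -0.33 (adjusted p = 1.09e-15, lowest 4.73e-21, adjusted p = 0.312 with an estimated correlation). Mitosis genes fell in 8 of 29 and 20 adjusted over the list alone, with a median of -0.35 (adjusted p = 1.79e-13, lowest 2.45e-23, adjusted p = 0.312 with an estimated correlation). AURKB is 1 of them (-0.54), a call that ended without monolayer replicate 3 (0.0618) and returned replicates 1 and 2 (0.0677 and 0.0528). Monolayer replicate 2, with a mean log2 level of 7.80 over the mitosis list, lay within the returned range of 7.62 to 7.81, and at 7.93 over the replication list it lay near the returned maximum of 7.86. In the core histone list the linker histones H1-5 (-0.92) and H1-2 (-0.62) and the core histone H3C2 (-0.60) fell, 3 of 22, against 15 lower and 1 higher adjusted over the list alone (adjusted p = 2.02e-08, lowest 1.52e-11, adjusted p = 0.312 with an estimated correlation). H1-5 ended without monolayer replicate 3 (0.0621) and returned replicate 1 (0.0581), H1-2 without monolayer replicate 3 (0.0741), and H3C2 without each array but returned replicates 1 and 2 (0.066 to 0.137).

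Metabolic lists were lower in returned cultures than in monolayer as well. Hypoxia-induced genes fell in 9 of 34, such as PFKFB4 (-0.98), and SLC2A1 and STC2 rose (median -0.23, adjusted p = 1.73e-06, lowest 5.19e-13, adjusted p = 0.507 with an estimated correlation, 0.113 by fry; adjusted over the list alone 15 fell and 2 rose). The glycolysis genes that fell were PFKP (-0.79), ALDOC, ENO2 (-1.02) and PFKL (-0.58), 4 of 16, against 10 lower and 1 higher adjusted over the list alone (adjusted p = 2.48e-08, lowest 3.19e-15, adjusted p = 0.312 with an estimated correlation). ALDOC ended without monolayer replicate 3 and returned replicate 1 (0.0521 and 0.0732), PFKL without these and returned replicate 3 (0.0706, 0.0711 and 0.0654), and ENO2 without each array but returned replicate 2 (0.0772 to 0.141). Of 37 genes of complex I and oxidative phosphorylation 1 was lower, the cytochrome c oxidase subunit COX5B (-0.33), also 1 adjusted over the list alone (adjusted p = 0.00717, lowest 0.00174, adjusted p = 0.312 with an estimated correlation). The list's call ended with array weights (0.0814) and without monolayer replicate 1 (0.0525), and that of COX5B without each of the other 8 arrays (0.0507 to 0.103).

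Another 3 lists were called lower in returned cultures by small margins. Cholesterol synthesis had 0 of 18 members past limma's test, and also 0 adjusted over the list alone, with 6 lower at an unadjusted p under 0.05 (adjusted p = 0.0247, lowest 0.00519, adjusted p = 0.577 with an estimated correlation, 0.141 by fry). Its call ended without variance moderation (0.0641), without monolayer replicate 1 (0.131) and without returned replicate 1 (0.197). Among 24 fatty acid genes ELOVL7 (-0.57), SCD and ACSL1 (-0.35) fell and ME1 rose, against 5 lower and 2 higher adjusted over the list alone (adjusted p = 0.0277, lowest 0.000387, adjusted p = 0.526 with an estimated correlation, 0.1 by fry). That list's call ended with array weights (0.167) and without monolayer replicate 1 (0.079), monolayer replicate 2 (0.0952) and returned replicate 3 (0.137), and the single call of ACSL1 without returned replicate 1 (0.0523). Among 27 epithelial genes CDH1, KRT8 (-0.43) and LLGL2 (-0.36) fell, against 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.0391, lowest 0.029, adjusted p = 0.526 with an estimated correlation, 0.123 by fry). This list's call ended with array weights (0.111), without variance moderation (0.0651), without the third of genes with the lowest mean level (0.0803), without monolayer replicate 2 (0.186) and without returned replicates 1, 2 and 3 (0.0553, 0.061 and 0.0604), KRT8 ended without monolayer replicate 3 (0.0683) and returned replicates 1 and 2 (0.0746 and 0.0638), and LLGL2 without each array but monolayer replicate 1 (0.0552 to 0.131).

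Several lists that separated spheroids from monolayer were not called between returned cultures and monolayer. Actin and SRF targets had 0 of 19 members past limma's test (3 higher and 1 lower at an unadjusted p under 0.05, list adjusted p = 0.918). NF-kB targets had 0 of 27 past it (5 higher at an unadjusted p under 0.05, 2 adjusted over the list alone, list adjusted p = 0.275). In the ALDH family ALDH1A1 and ALDH1L2 (1.04 ± 0.086) rose, 2 of 19, or 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.978). The secretory antiproteinase SLPI rose by 1.31 and the immunoglobulin receptor PIGR fell by 0.89, and neither the secretory list nor any list of other cell types was called. In 12 of the 39 lists, each not called, the median, the mean and the test differed in sign.

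**Figure D3:**
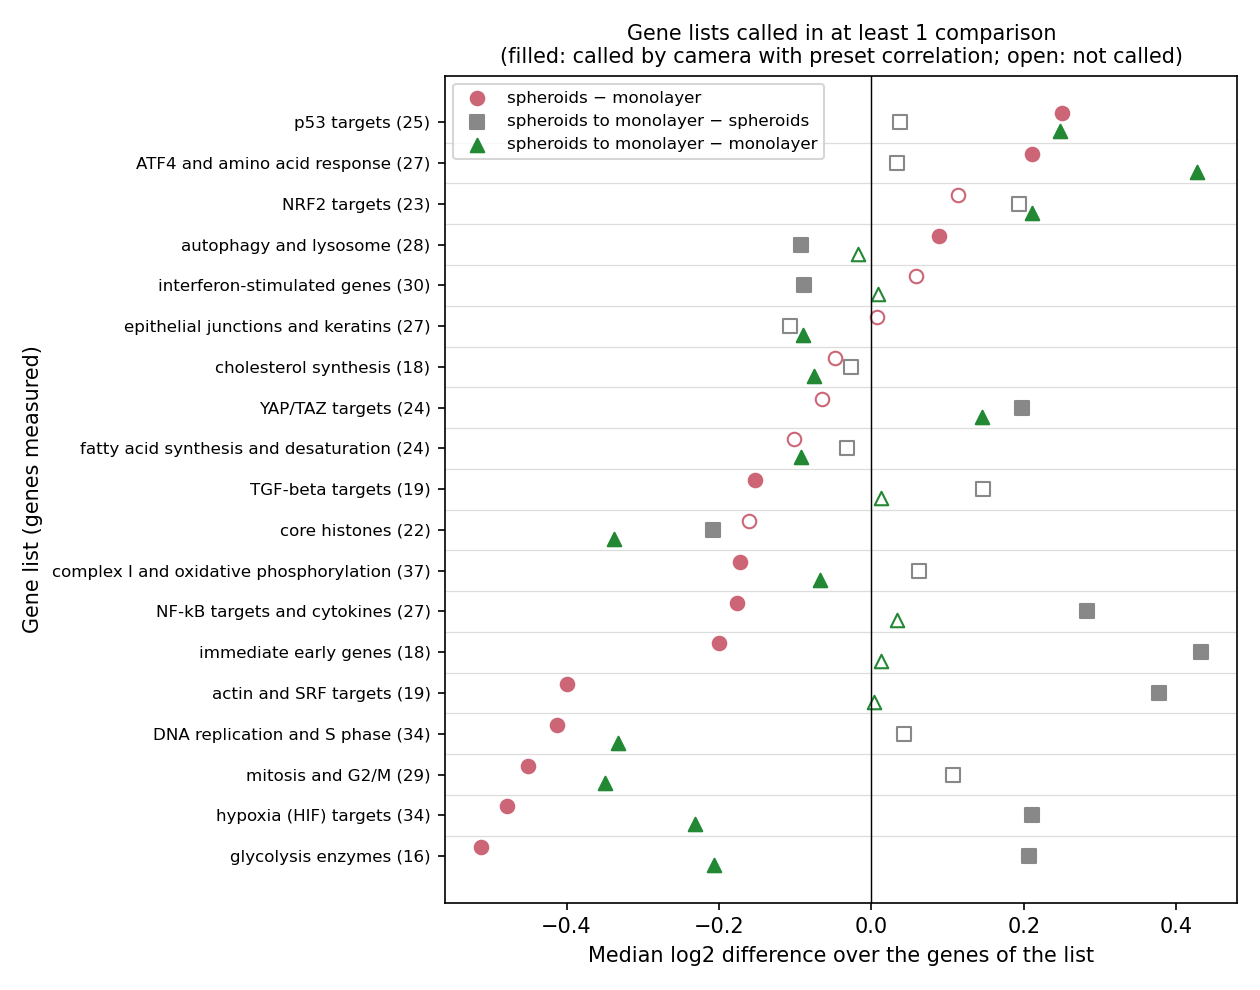
Median log2 difference of each called gene list, with 1 point per comparison, filled where camera called the list at its preset correlation, and the number of measured members beside each name. The hypoxia list lies at -0.48 in spheroids against monolayer and -0.23 in returned cultures against monolayer, and the p53 list at 0.25 in both.

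Of the 3365 genes that differed between spheroids and monolayer, 1789 (53.2%) moved back toward monolayer in returned cultures, 10 moved further away and 1566 showed no call in either direction. KIT kept 8.15% of its log2 difference, CD44 12%, PDK4 20.04% and NTS 27.6%, whereas ALDH1A1 kept 73.9%, PROM1 66.8% and KRT24 81.6%. Of the genes that differed by at least 2-fold, 289 of 331 (87.3%) moved back, with a median of 24.0% of the difference kept. The count of 1789 fell to 1144 without spheroids replicate 2 and to 1191 without variance moderation.

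A call in the same direction remained against monolayer for 324 genes (9.63%), 149 higher and 175 lower, and 222 of these had no call between returned cultures and spheroids. Among the 222, H2BC12, ATP10D, CHAC1, ALDH1L2, MAP1B and SLFN5 were higher and KRT24 and NRN1 lower, with 78.4% to 128.1% of their differences kept. The 324 became 151 without monolayer replicate 3, 197, 198 and 197 without spheroids replicates 1, 2 and 3, and 119, 213 and 211 without returned replicates 1, 2 and 3. It was 77 with only the groups compared in each fit, 80 without variance moderation and 750 with array weights. Another 44 genes passed the monolayer level, such as PI3, LRRN4 and SLC7A5 upward and PIGR, ITGA4 and HLA-DMB downward, the last lost without returned replicate 1 (0.0511).

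Both comparisons behind these counts use the same spheroid or monolayer arrays, which alone makes differences appear related. Across genes the spheroid difference correlated with the change on return at r = -0.81 and with the returned difference from monolayer at 0.48, where arrays simulated with no change gave -0.50 and 0.50. Covariances were -0.078 and 0.030 observed, against -0.0057 and 0.0057 simulated, so they differed by -0.073 and 0.025. Arrays simulated with full return gave 3983 to 4217 genes moving back and at most 1 kept, and arrays with no change gave at most 1 moving back and 0 kept, in 20 draws tested with limma. The full-return draws took the observed group means as true, and more genes moved back in them than the 3365 called between spheroids and monolayer. The observed 1789 can therefore not be read as a share of the simulated counts. By overlap, 967 genes higher in spheroids were lower on return against 121.4 for independent lists, and 822 lower ones were higher against 95.4. This balance follows the scaling too, with 741 and 1094 after median centring. For genes kept away from monolayer the overlaps were 149 against 22.1 and 175 against 22.5. With 3 arrays a group cannot be divided into parts of at least 2 arrays, so part of the excess may come from the shared arrays.

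**Figure D4:**
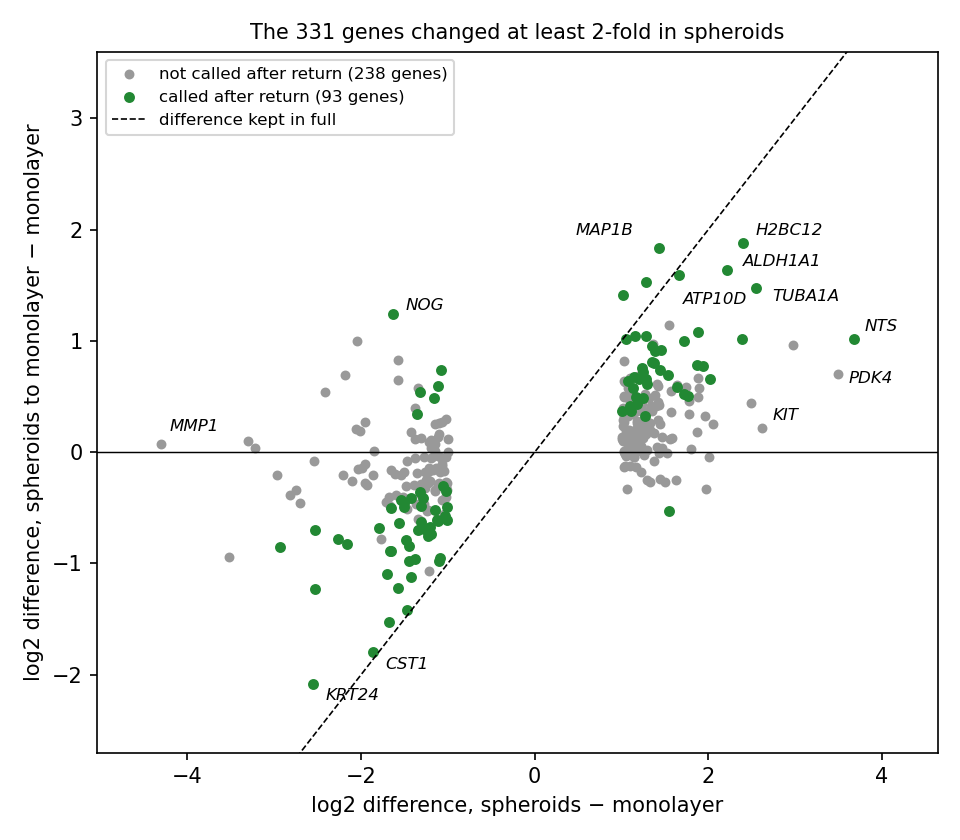
Each point is 1 of the 331 genes at least 2-fold changed in spheroids, with its log2 difference from monolayer in spheroids (horizontal) and in returned cultures (vertical); the dashed line marks a difference kept in full. Of the 93 genes called against monolayer after return, 86 lie on the same side of 0 as in spheroids, ALDH1A1 among them at 1.63, and 7, NOG among them, on the opposite side, while the other 238 were not called.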

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

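Of the alternatives, array weights were chosen only after the results were seen. Over single genes and alternatives other than leaving out an array, 2651 results kept their direction and side of the threshold, 172 lost the call, 2 gained one and 4 reversed, and no list reversed. Without variance moderation the count of genes was 1528 between returned cultures and spheroids, 112 between returned cultures and monolayer (22 at least 2-fold) and 2119 among the 3 groups, with 1191 returned and 80 kept. With only the groups compared it was 108 (24 at least 2-fold) and 77 kept. Array weights gave 1120 and 750 kept and turned FZD7, returned minus monolayer, to 0.114. Median centring turned CTNNB1 to -0.007 and 0.05 and HIF1A to 0.04. The estimated correlation left 0, 0 and 1 lists, and fry 22 and 18 in the comparisons with spheroids. Among genes of at least 2-fold 87.31% returned. The cause was not tested for these. Leaving out 1 array gave 2355 to 3376 genes between spheroids and monolayer, 1506 to 3093 and 183 to 557 in the later comparisons, 2184 to 3766 among groups, 1144 to 2101 returned and 119 to 408 kept. Reversals there were FZD7 (-0.148 to 0.057) and HIF1A (-0.008 to 0.217) in returned minus monolayer, and HIF1A (-0.055 to 0.03), CTNNB1 (-0.018 to 0.027) and MKI67 (-0.168 to 0.072) in returned minus spheroids, none past the threshold. A replicate block gave 3203, 2116 and 388 genes. Whether the numbers pair the arrays could not be told with 3 arrays per group. Deviations from the group means correlated at -0.091 to 0.122 between same-numbered arrays and at -0.116 to 0.107 between others. Of the 9 arrays, 5 correlated best with an array of their own number. Low levels cannot be set against background.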

Other observations

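Chosen only after the result was seen were the tests of leftover spheroid cells, of the monolayer format and of simulated shared arrays, and the FOXO target and protocadherin lists, drawn up once the largest changes were known.

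Protocadherin beta genes, clustered cell adhesion genes, were higher in spheroids as a family. Of 16 measured, 12 rose (median 1.05, camera p = 9.68e-13, 0.000259 with an estimated correlation), 11 fell again in returned cultures (median -0.81, camera p = 1.44e-10) and 4 stayed above monolayer, PCDHB8, PCDHB11, PCDHB14 and PCDHB16. Without the 4 seen at the outset, 8 of 12 rose (camera p = 3.3e-07, 0.0022 with an estimated correlation), but the 4 that stayed above monolayer are the ones seen at the outset, and the other 12 gave a camera p of 0.0175 there, 0.0551 with an estimated correlation. PCDHB1, PCDHB5, PCDHB7 and PCDHB15 did not pass the test (-0.11 to 0.13). The members are close paralogs, and cross-hybridisation between them was not tested.

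In returned cultures 121 genes were called against monolayer that were not called in spheroids, 59 higher and 62 lower, and 80 of them also differed from spheroids. Picked after their values were seen, CCND2 (1.35), NHERF1 (1.22), SERPINE2 (1.21), TGFA (1.13) and NRCAM (1.10) were higher, and LOXL2 (-0.73) and ID1 (-0.76) lower.

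The hypoxia and glycolysis lists were lower in spheroids than in monolayer. Against a shift that depends on brightness, none of 10000 random lists matched on mean level had a median as low for hypoxia (1e-04, the smallest these draws can give) or for glycolysis (1e-04), and against a single divergent array the hypoxia median lay no nearer to 0 than -0.414 when each array was left out. After a completed return, the monolayer format alone would place returned cultures at the monolayer level. Their glycolysis median was -0.207 (adjusted p = 0.00576 by fry, 0.312 by camera with an estimated correlation), with mean levels of 9.98 to 10.14 against 10.35 to 10.44 in monolayer. Culture duration is not given, so the format with an unfinished return stays open for both lists. For hypoxia a completed return stays open too: the median was -0.232, but the call ended by fry (0.113) and with an estimated correlation (0.507). Returned replicate 2 also had a mean hypoxia level of 8.03, close to the monolayer range of 8.06 to 8.14. For glycolysis the call was lost with an estimated correlation as well. A completed return is thus not excluded there, though fry called that list and its mean levels did not overlap between the groups. As a hypothesis, monolayer cultures may have been short of oxygen at harvest or spheroids may use less glucose, which density, medium and oxygen records would decide, and both list calls in spheroids are lost with an estimated correlation.

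Part of the spheroid difference was kept in returned cultures, for ALDH1A1 among others. Leftover spheroid cells would keep 1 share for all genes on the linear scale, but over 173 genes at least 2-fold higher in spheroids the shares spanned 25.68 percentage points between quartiles, where 200 draws with the fitted errors of all groups and 1 common share gave 6.72 to 11.1. ALDH1A1 kept 59.0% (standard deviation 16.3 percentage points over the 3 returned arrays), exceeded by 12 of the 173. Of the 8 genes raised at least as much, NTS, PDK4, THSD7A, KIT and TCP11L2 kept 3.36% to 13.25%, PCDHB16 24.2%, TUBA1A 38.6% and H2BC12 62.4%. Leftover cells at a share as low as that of KIT stay open (3.36%, standard deviation 4.31 percentage points over the 3 returned arrays). A larger share stays open if the other cells held KIT below the monolayer level. Of the 173 genes 1, DCLK1 (-15.85%), was called below monolayer in returned cultures. The 200 draws held random error alone, so a compression of ratios that differs between genes is not in their span. Independent errors of the shared monolayer arrays kept at most 1 gene in simulated full return, against 324 observed (77 to 750 over the alternatives). Because these errors were drawn separately for each gene, the simulation cannot cover an array that deviates in many genes together. Monolayer replicate 2 stood apart in that way, so an effect of the shared arrays stays open. A candidate explanation is that ALDH1A1 and some other genes return more slowly or less fully than the rest, a hypothesis that returned cultures sampled at several times would decide, and selection of cells or a difference in culture time was not tested.

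PDK4, KLHL24 and SESN3, higher in spheroids by 3.49, 1.78 and 1.64, are targets of FOXO transcription factors, which insulin and growth factor signals keep out of the nucleus. The other 22 measured targets were higher as a list (median 0.49, 12 up and 2 down, camera p = 1.54e-05, 0.00465 with an estimated correlation), among them BCL2L11 (1.28), TXNIP (0.82), CDKN1B and IRS2, with FBXO32 (-0.80) and KLF15 (-0.36) lower. Of the 22, 4 also sit in the fixed lists, and the naming rule had already picked BCL2L11, SESN1 and GABARAPL1 from those lists. The p-values of the 22 may thus not be independent of values already seen. None of 10000 random lists matched on mean level had a median as high (1e-04, the smallest these draws can give). In returned cultures 9 of the 22 fell and GADD45A rose by 0.55 (camera gave 8.81e-05). As a hypothesis, a wider rise of FOXO targets may reflect weaker growth factor signalling in spheroids, which levels of phosphorylated AKT and of nuclear FOXO proteins would decide and no measurement here tests.

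Other splits of the arrays were tried for each count. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3365, 2360 and 489 genes where the highest other split gave 0 in each comparison, and 1 split of 10, the real one, reached the real count. It gave 12 lists where the highest other gave 8 for spheroids against monolayer (1 split as high), 9 where another gave 10 for returned cultures against spheroids (2 splits as high) and 13 against 7 for returned cultures against monolayer (1 split as high). For the 3 groups 1 of 100 splits drawn, the real one, reached 3357 genes (highest other 1721), so a random labelling of these arrays is unlikely to give that count. Likewise 1 of 100 reached 1789 genes moving back (highest other 0). Splits that mix the groups widen the spread within groups, so a low count there was fixed in advance and does not test the return. Replicates may be technical, and splits of these arrays cannot address chance between cultures.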
